A study of Mus musculus with 6 samples.

How the data were processed

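Polyadenylated RNA of 6 libraries was sequenced, 3 from cultures that received a control shRNA and 3 from cultures that received an shRNA against Samd14. Per the labels' protocols, progenitors were enriched from E14.5 fetal liver, infected directly after isolation and grown for 3 days, and 200000 CD71-negative, Ter119-negative cells were lysed per library. The submitters' processing notes name CASAVA 1.8.2, Bowtie 1.0.1, RSEM 1.2.15 and the mm10 build, without their roles or settings. The annotation release, trimming, read length and use of strand are not given in the sources used here. The target of the control shRNA and the sequences of both hairpins are not given there either.

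Per the file headers, the authors deposited 1 RSEM gene table per library with expected counts, TPM, FPKM and the length and effective length of each gene. An expected count is a sum of reads in which a read that maps to several genes is shared between them in proportion, so genes with near-identical copies are less certain. TPM and FPKM, as deposited by the authors, are scaled per 1000000 transcripts, and per kilobase and 1000000 fragments. FPKM was read only to check it against TPM; rescaled to the sum of TPM it differed from TPM by at most 1.23% at a TPM of 1 or more. Each table listed 24376 Ensembl gene IDs, of which 23580 had a symbol in GENCODE M21 (GRCm38, the assembly of mm10) and 796 had none. Gene coordinates were taken from that annotation. Hbb-b1, Hbb-b2 and Ahsp had no ID under these symbols and were not analysed here.

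Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes with enough counts were kept with filterByExpr on the groups (minimum count 10, minimum total 15), which left 12670, and 6432 IDs were at 0 in all libraries. Library sizes were scaled with TMM factors, between 0.986 and 1.021. Dispersions were estimated robustly, the biological coefficient of variation was 7.52%, and the groups were compared with the two-sided quasi-likelihood test (glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment over all tested genes. The standard error is the absolute log2 fold change divided by the square root of the F statistic. CPM are TMM-scaled counts per 1000000; means are given with the SD of 3 libraries. With 20584169 to 26462797 counts per library, 3 counts correspond to 0.113 to 0.146 CPM, so that genes near 1 CPM rest on few reads.

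Gene lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, two-sided, adjusted over 22 lists; camera with an estimated correlation and fry were run beside it. With the estimated correlation no list passed. The test design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Samd14, Kit, Gata2, Gata1, Tfrc and Ppp1r9b. Among genes with an adjusted p under 0.05 whose groups do not overlap, it names in each direction the 10 with the smallest p and the 6 with the largest change at a mean of 1 CPM or more, skipping predicted genes. In each list it names up to 4 members past the threshold over all genes or, where none passed, the member with the smallest p. The lists of stem cell and Kit pathway genes share Kit. A withheld item is not reported here.

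On simulated counts with the means and trended dispersions of these data, 5 sets with 200 changed genes each, the test found 40.1% of 1.25-fold, 74% of 1.5-fold and 90.6% of 2-fold changes, and 4.8% of its calls were unchanged genes. With dispersions that varied from gene to gene the last share was 7.2%. Camera with the preset correlation found 15 of 15 lists shifted by 0.3 on the log2 scale and 0 of 85 unshifted lists. The simulated genes were drawn independently, so this does not show how often camera calls unshifted lists whose genes vary together. In these data the estimated correlation was 0.596 for glycolysis and hypoxia genes and 0.338 for cholesterol genes. Libraries of a group were compared for duplicates: their counts differed by a chi-square per gene of 5.76 to 12.31, far above sampling noise, so each was counted once.

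Words of 7 bases were searched in the longest annotated 3′ UTR of each gene (GENCODE M21 transcripts, at least 50 bases), which covered 11882 of the tested genes. For each of 15903 words present in at least 100 genes, the signed edgeR statistic, limited to 6 in size, was regressed on presence of the word with UTR length and GC content as covariates, and the largest t was set against 100 shuffles of the statistic. In simulated data 10 of 10 planted words were found. The words CTGATTA, TGATTAA, CAAGTGT and AAGTGTA were found in this search and are quoted beside genes as measured facts.

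Alternatives were other size factors (RLE, upper quartile), no filter or a filter of 1 CPM in 3 libraries, effective-length offsets, a block for the replicate number, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) of genes with a TPM of at least 1 in 3 libraries, an adjusted p under 0.01, a minimum fold change of 1.5 (glmTreat), and each library left out in turn. Analyses without both libraries numbered 3 and of genes without the 4 words were added after the data were seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the sequence search.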

Results

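Gene expression was measured by RNA sequencing in blood progenitors from C57BL/6 mouse E14.5 fetal liver. The progenitors were infected with a retrovirus carrying either a control short hairpin RNA (shRNA) or an shRNA against Samd14, and cultured for 3 days. A short hairpin RNA is processed in the cell into a small RNA that lowers the transcripts it pairs with. From each culture 200000 cells negative for CD71 and Ter119, surface proteins of maturing erythroid cells, were sorted before RNA extraction. Each group held 3 libraries. The control libraries held 20584169, 23294223 and 24069711 estimated counts, and the shSamd14 libraries 25344092, 23862151 and 26462797. The labels do not say that the 3 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

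Samd14 (ENSMUSG00000047181; chromosome 11, 95009879 to 95026087, plus strand, mm10), which encodes a sterile alpha motif protein, was lower in all 3 libraries that received its shRNA. The control libraries held 82.0, 82.1 and 83.8 counts per 1000000 (CPM), and the shSamd14 libraries 41.9, 38.8 and 39.4 CPM. The group means were 82.6 ± 1.04 and 40.0 ± 1.64 CPM (SD, n = 3 each), 0.484 of the control level. The log2 fold change was -1.05 (SE 0.06), with an adjusted p of 4.69e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ppp1r9b, a neurabin family member that lies just upstream on the same strand of chromosome 11 (94991035 to 95006899), had a log2 fold change of 0.02 (SE 0.07, adjusted p = 0.926 in the same edgeR test), and the sign of this value turned when control replicate 3 (-0.01), shSamd14 replicate 1 (-0.008) or shSamd14 replicate 3 (-0.022) was left out.

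The design compares the transcriptomes of the groups, to ask which genes differ when Samd14 is lowered in these progenitors. Rab1a, a GTPase of transport from the endoplasmic reticulum to the Golgi, had the smallest p of all genes: it rose from 58.0 ± 2.18 to 182 ± 9.71 CPM (SD, n = 3 each), 3.14-fold. Mtap, an enzyme of methionine salvage, rose 1.99-fold. Serinc3, a membrane protein, rose from 740 ± 15.6 to 1300 ± 34.5 CPM, and Rbm38, an RNA-binding protein, rose 1.79-fold. Ptpn11, which encodes the tyrosine phosphatase SHP2 of receptor tyrosine kinase signalling, rose 1.55-fold, from 131 ± 4.26 to 202 ± 3.9 CPM. Utp6, Oxnad1, Elmod2, the red cell water channel Aqp1, and Prkar1a, a regulatory subunit of protein kinase A, completed the 10 named genes with the smallest p among those that rose, at 1.64-, 1.59-, 1.72-, 1.54- and 1.43-fold. The adjusted p of these 10 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay between 2.11e-09 for Rab1a and 0.000253 for Prkar1a. The annotated 3′ untranslated region (UTR) of 9 of them, all but Aqp1, held the 7-base word CTGATTA or TGATTAA, against 14.4% of searched genes that did not pass the test.

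Among the genes that fell, Samd14 had the smallest p. Uba3, the catalytic subunit of the NEDD8-activating enzyme, fell from 89.4 ± 5.76 to 56.0 ± 4.75 CPM, 0.626 of the control level. Spred2, an inhibitor of Ras and ERK signalling, fell from 42.8 ± 3.05 to 27.2 ± 1.16 CPM, 0.634 of the control level. Bach1, a heme-regulated transcriptional repressor, fell to 0.701, and Nckap1, a subunit of the WAVE actin regulator, to 0.668. Prkaa1, a catalytic subunit of AMP-activated protein kinase, fell to 0.733, and the antiproliferative gene Tob1 to 0.672. Commd4, Ccdc47 and Cmtm6 fell to 0.625, 0.657 and 0.708 of the control level. The adjusted p of these 10 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay between 4.69e-07 for Samd14 and 0.00126 for Tob1. The annotated 3′ UTR of 8 of them, Samd14 included and all but Prkaa1 and Tob1, held CAAGTGT or AAGTGTA, against 22.2% of searched genes that did not pass the test.

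Further genes were named for the size of their change. Fsd1l rose from 0.739 ± 0.291 to 2.15 ± 0.269 CPM (SD, n = 3 each), with a log2 fold change of 1.55 (SE 0.27). Nmnat2, an enzyme of NAD synthesis, rose from 1.10 ± 0.35 to 2.71 ± 0.196 CPM. Slamf1, which encodes the stem cell marker CD150, rose 2.10-fold, to 3.80 ± 0.557 CPM, and the amine oxidase Aoc3 and the protease inhibitor Serpina3i rose 2.18- and 2.05-fold. Tead3, a transcription factor of the Hippo pathway, fell from 2.18 ± 0.487 to 0.915 ± 0.206 CPM. Pnmt, the enzyme that makes adrenaline, Mgarp, the phospholipid transfer protein gene Pltp and the Rac exchange factor gene Prex2 fell to 0.43, 0.445, 0.49 and 0.499 of the control level. Serpina3i belongs to a family of similar copies whose reads can be split between members. Pltp overlaps Ctsa and Oxnad1 overlaps Dph3 on the opposite strand, and Ccdc47 overlaps Strada on the same strand, so these values are uncertain. Of the 10 genes from Fsd1l to Prex2, all but Fsd1l missed the threshold of edgeR's quasi-likelihood test in some of the 6 fits with 1 library left out: Serpina3i in all 6 (adjusted p 0.0773 to 0.191), Aoc3 in 5, Prex2 in 4, Pnmt in 3, Slamf1 and Tead3 in 2 each, and Nmnat2, Mgarp and Pltp in 1 each. Prex2 had a log2 fold change of -0.698 without control replicate 1, against -1.004 with all libraries. In the 3′ UTR, Fsd1l held CTGATTA, TGATTAA, CAAGTGT and AAGTGTA, and Slamf1 held CTGATTA and TGATTAA. Aoc3, which rose, held only AAGTGTA, and Nmnat2, Serpina3i, Tead3, Pnmt, Mgarp, Pltp and Prex2 held none of these words.

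In all, 327 of the 12670 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 167 higher and 160 lower in shSamd14. The changes were small: the median absolute log2 fold change of these genes was 0.43, 73 changed by at least 1.5-fold and 16 by at least 2-fold. The 3 shSamd14 libraries lay wholly above or below the 3 control libraries for 20.7% of tested genes, where chance gives 10%, and for all 327 genes that passed. CTGATTA or TGATTAA occurred in the 3′ UTR of 100 of the 167 genes that rose, and CAAGTGT or AAGTGTA in that of 91 of the 157 searched genes that fell. Without control replicate 1 the count was 153 genes and without shSamd14 replicate 2 it was 128; without shSamd14 replicate 1, 106 genes were higher. Of the 47 named genes that passed, 26 also passed with each library left out in turn, among them the 10 of smallest p in each direction, and 21 did not.

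**Figure D1:**
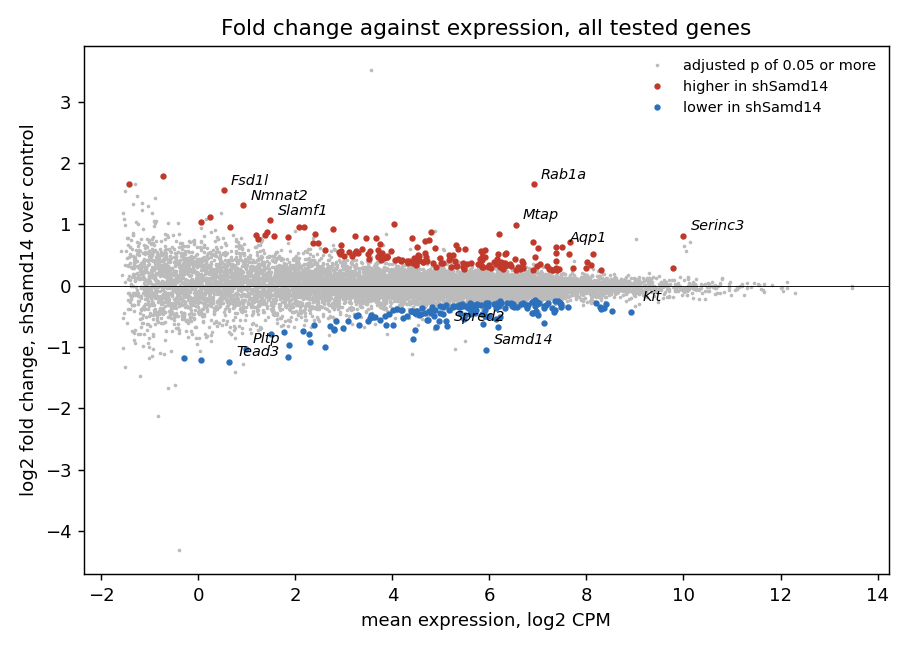
Log2 fold change of shSamd14 over control (vertical axis) against mean expression in log2 CPM over the 6 libraries (horizontal axis), 1 point for each of the 12670 tested genes. Red points are the 167 genes higher and blue points the 160 genes lower in shSamd14 at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and grey points are the other genes; Rab1a stands at 1.65 and Samd14 at -1.05, while Kit (-0.33) did not pass.

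Genes of megakaryocytes and platelets had the highest median of the 22 lists. Of the 29 tested members of this list, 10 rose, none fell, and 28 had a positive log2 fold change. Rab27b, a GTPase of platelet granule secretion, rose 1.39-fold, the platelet chemokine gene Pf4 rose from 49.2 ± 3.99 to 66.1 ± 6.2 CPM (SD, n = 3 each), the platelet glycoprotein gene Gp5 rose 1.29-fold, and the lipoxygenase gene Alox12 rose 1.47-fold. A total of 20 members were higher when adjusted over the list alone. The summed expression of the members was 1220 ± 81 CPM in control and 1451 ± 33 CPM in shSamd14 libraries. The list's median log2 fold change was 0.38, and camera with a preset correlation of 0.01 gave an adjusted p of 1.23e-17 over 22 lists. The call was lost with adjusted p = 0.103 with an estimated correlation, and fry gave an adjusted p of 0.0226. Of the 10 genes that rose, only Alox12 held CTGATTA or TGATTAA in its 3′ UTR. Without shSamd14 replicate 2, all 4 genes named here missed the threshold in edgeR's quasi-likelihood test (adjusted p 0.0731 for Rab27b, 0.0907 for Pf4, 0.113 for Gp5 and 0.102 for Alox12), with log2 fold changes of 0.452, 0.349, 0.331 and 0.568 against 0.478, 0.426, 0.363 and 0.558 with all libraries. Of the other 5 fits with 1 library left out, Alox12 missed it in 4, Gp5 in 2 and Pf4 in 1.

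**Figure D2:**
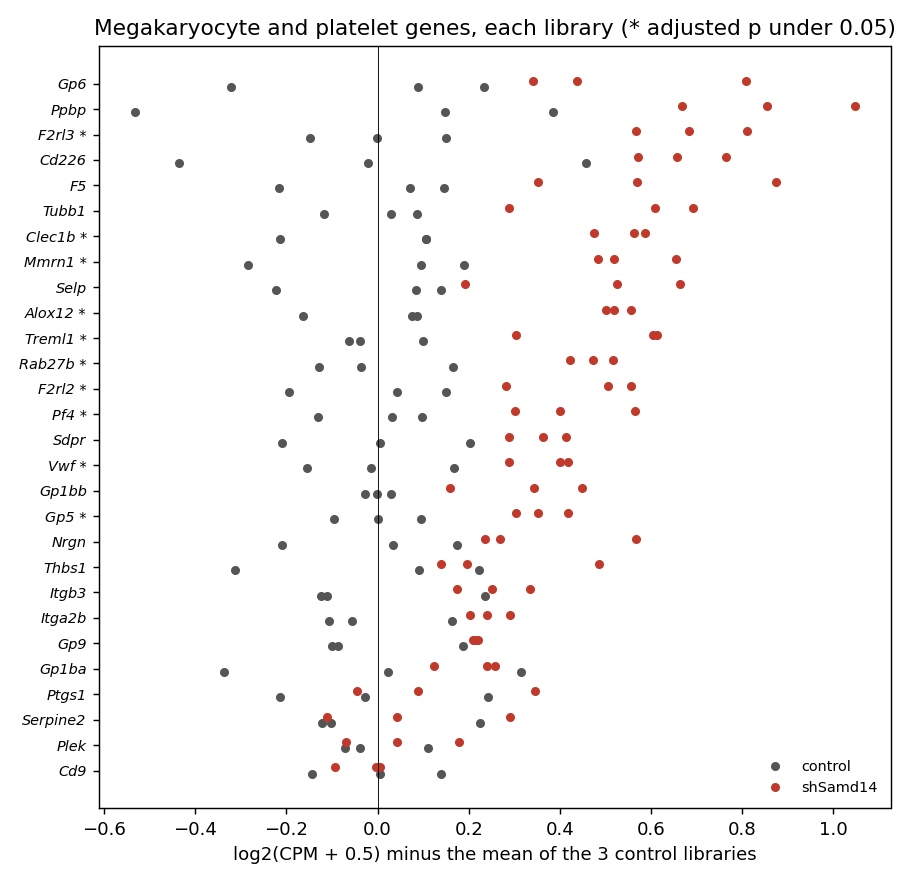
Log2(CPM + 0.5) of each library minus the mean of the 3 control libraries (horizontal axis) for 28 of the 29 megakaryocyte and platelet genes tested (vertical axis). Grey points are control and red points shSamd14 libraries, and an asterisk marks the 10 genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test.

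Genes of erythroid maturation lay higher by a smaller amount. Of 36 members, 4 rose and none fell: Aqp1 (1.54-fold), the carbonic anhydrase gene Car1 (66.8 ± 4.69 to 96.3 ± 8.22 CPM), the erythroid nuclear factor gene Hemgn (1.29-fold) and Tmcc2 (1.71-fold). There were 7 members higher and 1 lower adjusted over the list alone. None of the 4 held any of the words CTGATTA and TGATTAA in its 3′ UTR. Gata1, the erythroid transcription factor gene, had a log2 fold change of 0.08 (SE 0.06, adjusted p = 0.586 in edgeR's quasi-likelihood test) and Tfrc, which encodes CD71, one of -0.18 (SE 0.07, adjusted p = 0.239). The cells had been sorted as negative for CD71 and Ter119. The values of this list therefore do not describe the maturing erythroid cells of the cultures. The median of the list was 0.13, with an adjusted p of 3.41e-06 in camera with the preset correlation, adjusted p = 0.793 with an estimated correlation and 0.292 in fry. With 1 library left out in turn, Hemgn missed the threshold of edgeR's quasi-likelihood test in 5 of 6 fits (adjusted p 0.0519 to 0.134; log2 fold change 0.304 to 0.401 there, against 0.366 with all libraries) and Tmcc2 in 4 (adjusted p 0.0675 to 0.222; log2 fold change 0.606 to 0.752, against 0.773).

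Globin and heme synthesis genes varied widely between libraries and none of the 17 tested passed, adjusted over all genes or adjusted over the list alone. Hbb-bt, an adult beta globin, had 386 ± 117 CPM in control and 656 ± 83.9 CPM in shSamd14 libraries (adjusted p = 0.303 in edgeR's quasi-likelihood test). Globin copies are near identical, so how their reads were divided is uncertain. The list's median was 0.09 and its adjusted p in camera 0.0772 (adjusted p = 0.928 with an estimated correlation). It passed camera upward without control replicate 3 (median 0.153, adjusted p = 1.57e-06) and without shSamd14 replicate 2 (median 0.112, adjusted p = 0.0136).

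Regulators of stem and progenitor cells moved in both directions. Of 34 tested, Slamf1 rose and Lin28b, a fetal RNA-binding protein that blocks let-7 maturation, fell from 111 ± 8.99 to 89.6 ± 6.14 CPM (adjusted p = 0.0369 in edgeR's quasi-likelihood test). Kit, the receptor for stem cell factor, had 570 ± 81.2 CPM in control and 454 ± 27.4 CPM in shSamd14 libraries, a log2 fold change of -0.33 (SE 0.09) that did not pass (adjusted p = 0.0943), with all 3 shSamd14 libraries below all 3 control libraries. Gata2, which encodes a transcription factor of these progenitors, had 71.5 ± 7.87 and 85.1 ± 2.33 CPM, a log2 fold change of 0.25 (SE 0.08, adjusted p = 0.106 in edgeR's quasi-likelihood test). Adjusted over the list alone, 7 members were higher, Gata2 among them, and 3 lower, Kit among them (adjusted p = 0.0254 for each). The 3′ UTR of Kit held both CAAGTGT and AAGTGTA, that of Lin28b held CAAGTGT, and that of Slamf1 held CTGATTA and TGATTAA. The list's median was 0.09 (adjusted p = 0.0772 in camera, adjusted p = 0.928 with an estimated correlation), and it passed upward without shSamd14 replicate 1 (median 0.181, adjusted p = 0.000952 in camera). With 1 library left out, Lin28b missed the threshold of edgeR's quasi-likelihood test in 5 of 6 fits (adjusted p 0.0643 to 0.164; log2 fold change -0.362 to -0.269 there, against -0.304 with all libraries).

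**Figure D3:**
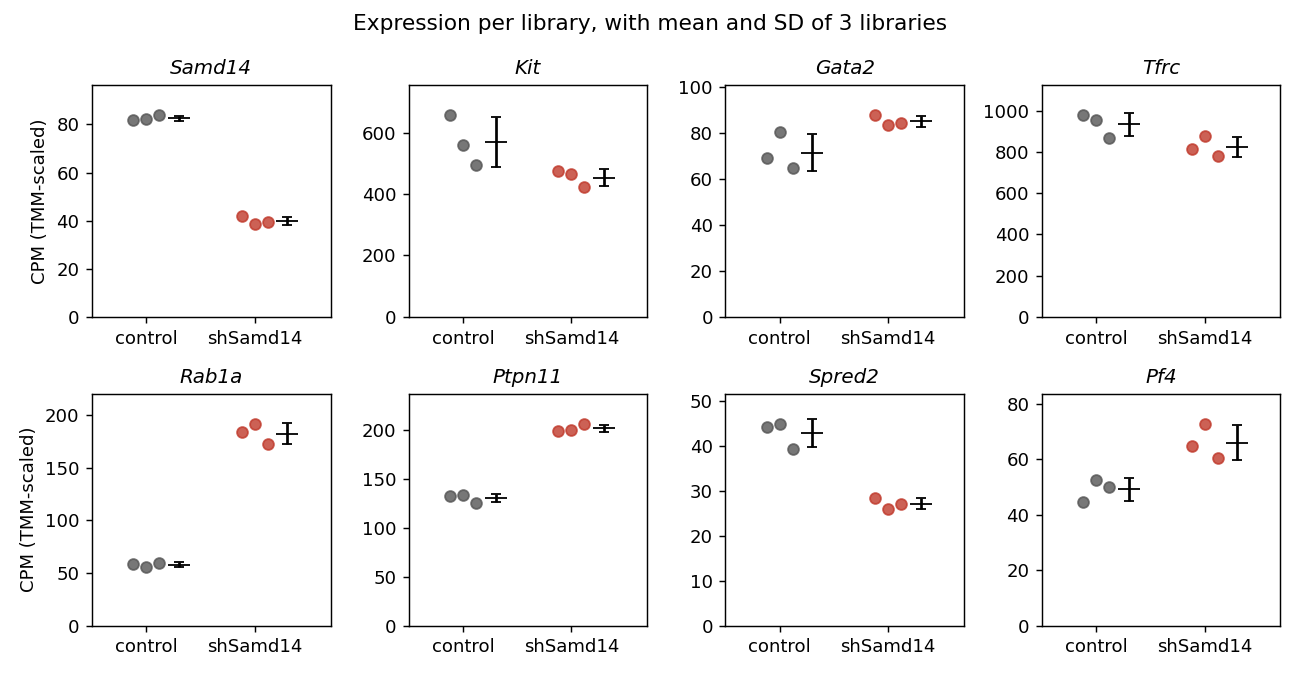
Expression in CPM, scaled by TMM factors (vertical axis, from 0), of 8 genes in each control (grey) and shSamd14 (red) library, with the mean and SD of the 3 libraries of a group beside the points. Samd14 and Spred2 were lower and Rab1a, Ptpn11 and Pf4 higher in shSamd14 at an adjusted p under 0.05 in edgeR's quasi-likelihood test, while Kit (0.0943), Gata2 (0.106) and Tfrc (0.239) did not pass.

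Components of Kit signalling and genes that respond to ERK, a kinase downstream of Kit, changed in a few single members, and neither list passed camera. In fry's test for changes in either direction, both lists had an adjusted p of 0.000295. Erythroid maturation genes had the same value. Further lists passed this test too, among them actin capping (0.0014), stem cell (0.00196) and megakaryocyte genes (0.0027), while others, such as neutrophil genes (0.629), did not. A few strongly changed members can carry this test, so it does not set these lists apart. Of 47 signalling components, Ptpn11 and the tyrosine kinase gene Src (1.88 ± 0.381 to 3.44 ± 0.516 CPM) rose, and none fell. When adjusted over the list alone, 3 were higher and 1, Kit, lower. Of 31 ERK-responsive genes, Spred1, an inhibitor of Ras signalling, and the ERK phosphatase gene Dusp6 rose 1.39- and 1.51-fold. Nr4a1, named after its value was seen, rose by 0.82 on the log2 scale (adjusted p = 0.0455 in edgeR's quasi-likelihood test). Spred2 and the antiproliferative gene Btg2 fell to 0.634 and 0.727 of the control level. Adjusted over the list alone, 3 were higher and 3 lower. The 5 genes that rose in these lists all held CTGATTA or TGATTAA in the 3′ UTR, and both Spred1, which rose, and Spred2, which fell, held all 4 words. The median of the signalling list was -0.01 while camera gave it an upward direction (adjusted p = 0.512), and the median of the ERK list was -0.001 with an upward direction (adjusted p = 0.817); with an estimated correlation both had an adjusted p of 0.928. Without shSamd14 replicate 2, Src (adjusted p = 0.127), Dusp6 (0.115) and Btg2 (0.157) missed the threshold in edgeR's quasi-likelihood test, with log2 fold changes of 0.857, 0.49 and -0.467 against 0.876, 0.595 and -0.459 with all libraries. Counting that fit, Btg2 missed it in 5, Src in 4 and Dusp6 in 3 of the 6 fits with 1 library left out.

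Genes of glycolysis and the hypoxia response lay lower in shSamd14: 25 of 26 members had a negative log2 fold change, with a median of -0.21. Of these, Ddit4, an inhibitor of mTOR complex 1 that is induced by hypoxia, fell from 138 ± 17.4 to 101 ± 9.85 CPM (SD, n = 3 each; adjusted p = 0.0408 in edgeR's quasi-likelihood test), and the other 25 did not pass. Adjusted over the list alone, 2 members were lower, Ddit4 and Pfkl, the latter named after its value was seen. The list had an adjusted p of 1.35e-07 in camera with the preset correlation, adjusted p = 0.928 with an estimated correlation and 0.579 in fry. The members summed to 17710, 16720 and 17620 CPM in the control libraries and to 17210, 15820 and 14720 CPM in shSamd14 replicates 1, 2 and 3. Without shSamd14 replicate 3 the median of the list was -0.11, while Ddit4 had a log2 fold change of -0.418, against -0.447 with all libraries, and an adjusted p of 0.133 in edgeR's quasi-likelihood test; Ddit4 missed the threshold in 3 further fits with 1 library left out (adjusted p 0.0952 to 0.138).

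Cholesterol synthesis and uptake genes also lay lower, with a median of -0.11 over 24 members, 22 of them negative. None passed over all genes, whereas 9 were lower when adjusted over the list alone; Msmo1, a sterol demethylation enzyme, had 209 ± 8.19 and 177 ± 16.7 CPM (adjusted p = 0.0949 in edgeR's quasi-likelihood test). Camera with the preset correlation gave an adjusted p of 1.36e-05, with adjusted p = 0.928 with an estimated correlation and 0.501 in fry. Without shSamd14 replicate 3 the median was -0.07.

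With all 6 libraries, no list of markers of other blood, liver or vessel cells passed camera, apart from the megakaryocyte and erythroid lists. Of 23 mast cell and basophil genes, Il1rl1, the receptor for interleukin 33, rose from 143 ± 18.3 to 189 ± 10.9 CPM (adjusted p = 0.0213 in edgeR's quasi-likelihood test); it missed the threshold in 4 of 6 fits with 1 library left out (adjusted p 0.0662 to 0.114; log2 fold change 0.343 to 0.398 there, against 0.405). With p adjusted over the list alone, 1 was higher and 1 lower. The list's median was 0.05 (adjusted p = 0.817 in camera, adjusted p = 0.943 with an estimated correlation). None of 30 neutrophil and granulocyte genes passed, over all genes or adjusted over the list alone (median 0.13, adjusted p = 0.512 in camera, adjusted p = 0.928 with an estimated correlation). Their summed expression was 4393, 4279 and 6821 CPM in control replicates 1, 2 and 3 and 4820, 5001 and 7065 CPM in shSamd14 replicates 1, 2 and 3. In each group, replicate 3 stood above the others. The list passed camera upward without control replicate 3 (median 0.378, adjusted p = 3.5e-06) and without shSamd14 replicate 2 (median 0.225, adjusted p = 0.0433). Ear6, a granulocyte ribonuclease with near-identical family members, had the smallest p of the list (log2 fold change -0.42, adjusted p = 0.28 in edgeR's quasi-likelihood test).

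None of 29 monocyte and macrophage genes passed (median 0.10, adjusted p = 0.574 in camera; without control replicate 3 the list passed, with a median of 0.292 and an adjusted p of 0.00252), and Vcam1 had 0.711 ± 0.0881 and 1.36 ± 0.333 CPM (adjusted p = 0.0951 in edgeR's quasi-likelihood test). The same held for 15 dendritic cell and MHC class II genes (median -0.06, adjusted p = 0.574 in camera; Clec10a log2 fold change -0.49, adjusted p = 0.119) and 6 lymphoid genes (median 0.09, adjusted p = 0.574; Nkg7 0.42, adjusted p = 0.427). None of 7 hepatocyte genes passed: the median was 0.25, the mean -0.03 and the camera direction downward (adjusted p = 0.817), and Ahsg had a log2 fold change of -0.74 (adjusted p = 0.284 in edgeR's quasi-likelihood test). Of 10 endothelial and stromal genes none passed (median -0.07, adjusted p = 0.647 in camera; Tek -0.33, adjusted p = 0.267). None of these 5 lists had a member past the threshold when adjusted over the list alone, and each had an adjusted p of 0.928 with an estimated correlation.

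Few cell cycle and stress genes passed. Rrm2, a subunit of ribonucleotide reductase, fell from 419 ± 9.82 to 315 ± 21.9 CPM (adjusted p = 0.00421 in edgeR's quasi-likelihood test) and was the 1 of 30 DNA replication genes to pass; its 3′ UTR held CAAGTGT. Adjusted over the list alone, 2 were higher and 1 lower (median 0.06, adjusted p = 0.437 in camera; 0.0351 without control replicate 2, upward). None of 30 G2/M genes passed, over all genes or adjusted over the list alone (median -0.02, adjusted p = 0.817; Ttk -0.15, adjusted p = 0.303 in edgeR's quasi-likelihood test). Of 30 p53 target and apoptosis genes, Bak1, an effector of mitochondrial apoptosis whose 3′ UTR held TGATTAA, rose from 65.9 ± 3.77 to 94.4 ± 6.45 CPM (adjusted p = 0.00104 in edgeR's quasi-likelihood test), and it was the 1 gene past the threshold adjusted over the list alone (median -0.05, adjusted p = 0.512 in camera). Bak1 overlaps Ggnbp1 on the opposite strand, and whether counting used strand is not given in the sources used here.

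None of 21 interferon-stimulated genes passed (median 0.03, camera direction downward, adjusted p = 0.963; Xaf1 -0.51, adjusted p = 0.215 in edgeR's quasi-likelihood test). Nor did any of 30 ATF4 and unfolded protein response genes (median -0.07, adjusted p = 0.0772 in camera and 0.000407, downward, without shSamd14 replicate 1; Nupr1 -0.91, adjusted p = 0.106 in edgeR's quasi-likelihood test) or 12 heat shock genes (median 0.02, adjusted p = 0.653 in camera; Hsph1 0.13, adjusted p = 0.363 in edgeR's quasi-likelihood test), and none of these 3 lists had a member past the threshold adjusted over the list alone. Of 25 genes of actin capping and the neurabin family, Capza2, an actin capping subunit whose 3′ UTR held CAAGTGT and AAGTGTA, fell from 220 ± 7.28 to 174 ± 11.9 CPM (adjusted p = 0.0102 in edgeR's quasi-likelihood test). Adjusted over the list alone, 2 were lower; the median was 0.03 with a downward camera direction (adjusted p = 0.817). With an estimated correlation, the G2/M list had an adjusted p of 0.943, the interferon list one of 0.972 and the other 5 lists, from DNA replication to actin capping, 0.928 each.

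**Figure D4:**
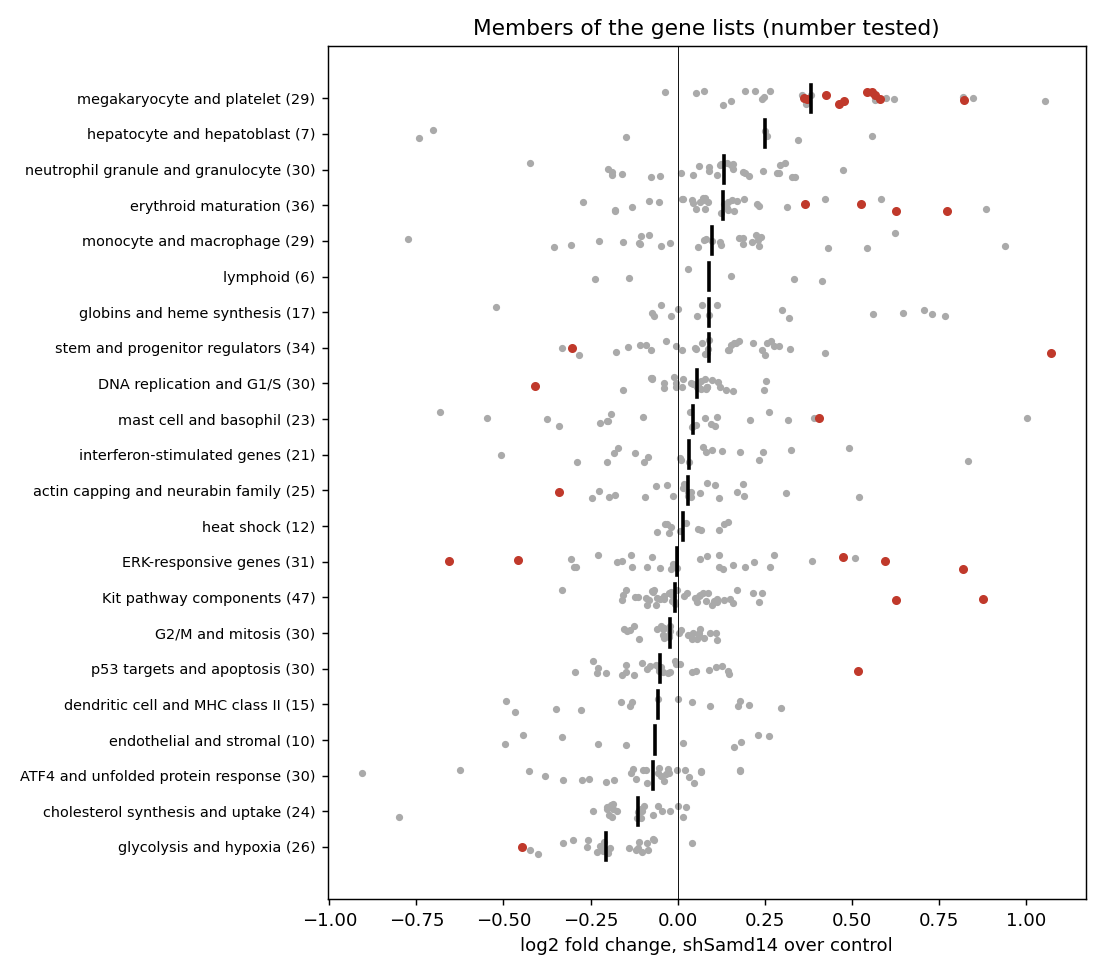
Log2 fold change of shSamd14 over control (horizontal axis) for each tested member of the 22 gene lists (vertical axis, with the number tested in brackets). Red points are members with an adjusted p under 0.05 over all genes in edgeR's quasi-likelihood test, grey points are the others, and black bars are list medians; the medians run from 0.38 for megakaryocyte and platelet genes to -0.21 for glycolysis and hypoxia genes.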

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

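The tests without both libraries numbered 3 and on genes without the 4 words were chosen after the data were seen. Samd14 stayed lower and past the threshold under every alternative that gave it a value. The count of 327 genes (167 higher, 160 lower; 51.1% higher) was 330 with RLE and 321 with upper-quartile factors, 282 with effective-length offsets, 273 with limma-voom, 414 with DESeq2 (6104 genes without an adjusted p) and 369 without both libraries numbered 3 (254 shared). It was 168 (106 higher, 62 lower; 63.1% higher) with limma on log2(TPM + 1), where the cause was not tested, 104 (61 and 43) at an adjusted p under 0.01 and 3 (2 and 1) for a minimum fold change of 1.5; the last pair are stricter by construction. Without a filter 261 genes were lower, with more genes tested. With each library left out the count ran from 128 to 283 (higher 63 to 133, lower 65 to 163), with 153 without control replicate 1 and 128 without shSamd14 replicate 2; fewer samples were then tested. The 8080 genes without the 4 words, Samd14 not among them, gave 65 (29 and 36) with p adjusted over these genes alone. Fewer genes were tested, and genes past the threshold were often left out: of the 324 searched, 116 had none of the 4 words. The replicate block gave 682 genes (322 higher, 360 lower), all 327 among them. Correlations of same-numbered libraries were -0.18, 0.26 and 0.47, and those of unlike numbers ran from -0.5 to 0.38. Summed neutrophil genes were highest in replicate 3 of both groups (6821 CPM in control, 7065 CPM in shSamd14). Summed globin and heme synthesis genes were lowest in replicate 2 of both (4253 and 6266 CPM). Summed glycolysis and hypoxia genes were lowest in unlike numbers, control replicate 2 (16720 CPM) and shSamd14 replicate 3 (14720 CPM). The labels do not say whether the numbers pair the samples, and these values do not settle it. In camera the replicate block also called 6 lists, adding globin (adjusted p = 1.43e-07) and neutrophil genes (5.87e-05). Of the 4 lists called, 0 passed camera with an estimated correlation (adjusted p 0.103 for megakaryocyte, 0.793 for erythroid, 0.928 for glycolysis and 0.928 for cholesterol genes). With directional fry 1 passed (adjusted p 0.292, 0.579 and 0.501 for the last 3). The estimated correlations were 0.076 for megakaryocyte, 0.138 for erythroid, 0.596 for glycolysis and 0.338 for cholesterol genes, against the preset 0.01. A higher correlation makes camera stricter. With an estimated correlation, camera also takes its degrees of freedom from the 6 libraries rather than from the genes, which makes it stricter too. For endothelial and stromal genes the estimated correlation was -0.041, below the preset, yet camera's unadjusted p rose from 0.441 to 0.466. How much of each loss came from the correlation and how much from the few libraries was not tested. All 4 passed with each library left out, when 4 to 7 of the 22 lists passed, 7 without control replicate 3. Without both libraries numbered 3 globin and neutrophil lists also passed, and without the words globin and ATF4 lists. Of 1033 values of 63 named genes, 901 kept direction and side, 108 lost and 20 gained the threshold; 4 reversed, all Ppp1r9b: -0.01 without control replicate 3, -0.008 and -0.022 without shSamd14 replicates 1 and 3, and -0.045 without both libraries numbered 3 (-0.022 to 0.072 with 1 library left out). Of the 47 named genes past the threshold, 14, 10 and 9 lost it without control replicates 1, 2 and 3, and 9, 19 and 9 without shSamd14 replicates 1, 2 and 3. Depth limits genes near 1 CPM most.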

Other observations

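The test of megakaryocyte genes against other cell type lists was chosen after their fold changes were seen; the tests of words, left-out libraries, length and GC content were written down before their results were seen, although the patterns they address had been seen. Fisher's tests, site medians, held-out parts and library pairs for the words were chosen after the words were found. The bootstrap intervals below resample genes and not libraries, so they do not measure the spread between libraries.

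The genes that rose and the genes that fell were marked by different short words in their 3′ UTRs. Over 11882 genes, CTGATTA was the word most strongly tied to higher values in shSamd14, followed by TGATTAA, which overlaps it by 6 bases, and AAGTGTA and CAAGTGT, which also overlap, were those most tied to lower values. Of the 167 genes that rose, 100 (59.9%) carried CTGATTA or TGATTAA, against 14.4% of genes not past the threshold (odds ratio 8.89, Fisher's exact test, two-sided, p = 6.65e-41) and 11.5% of genes that fell. Of the 157 searched genes that fell, 91 (58.0%) carried CAAGTGT or AAGTGTA, against 22.2% (odds ratio 4.82, Fisher's exact test, two-sided, p = 1.04e-21) and 24.6% of genes that rose. These p-values describe genes that had already been used to find the words. Unlike the search, these shares and the medians below take no account of UTR length and GC content. Genes with TATATCT, a word whose t of -4.7 in the search lay within the range of the shuffles, had a median of -0.043, against 0.012 without it. The medians below are therefore not effects of a word alone. Among the 50 genes of smallest p in each direction, 39 and 36 carried their words. Genes with both overlapping words joined as an 8-base site, and neither word of the other pair, had a median log2 fold change of 0.118 (95% bootstrap interval 0.087 to 0.162, 190 genes) and -0.077 (-0.098 to -0.056, 269 genes), against 0.014 for 8080 genes with none of the words. Again without the other pair, genes with CTGATTA but not the 8-base site had a median of 0.043 (0.022 to 0.062) and genes with TGATTAA but not CTGATTA one of 0.024 (0.009 to 0.04), while genes with CAAGTGT but not the 8-base site had -0.016 (-0.027 to -0.006) and genes with AAGTGTA but not CAAGTGT -0.054 (-0.061 to -0.04). With none of the 4 words in the 3′ UTR, genes with CTGATTA in the coding part had a median of 0.014 (-0.004 to 0.042, 274 genes) and genes with CAAGTGT there 0.005 (-0.008 to 0.018, 913 genes); TGATTAA and AAGTGTA alone in the coding part were not tested. Of the 324 searched genes past the threshold, 191 (59.0%) were higher with the first words or lower with the second, and 116 had none of the 4 words.

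Small RNAs made from hairpins lower transcripts whose 3′ UTR pairs with their seed, so hairpins with different seeds may leave such marks. The word most tied to higher values in shSamd14 had a t of 20.61, against at most 4.77 in 100 shuffles, and it ranked first in both held-out parts of the genes (t 13.33 and 15.76). This is what repression by the control hairpin, present only in the control libraries, would give, and as a hypothesis part of the 167 higher genes, Rab1a and Ptpn11 among them, may be released from the control hairpin rather than raised by loss of Samd14. The word most tied to lower values had a t of -10.75, against -5.24 at the extreme of the shuffles, and ranked first in both parts (t -6.52 and -8.7), but whether it belongs to the Samd14 hairpin stays open: AAGTGTA was found in none of the 3 annotated Samd14 transcripts, while CAAGTGT was found in 1, ENSMUST00000055947, at transcript bases 1607 to 1613 (coding part) and 3246 to 3252 (3′ UTR); 16.6% of all words searched occur in a Samd14 transcript. The hairpin sequences were not used here, so a microRNA of the cells that differs between the groups was not tested and stays open for both words.

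In each of the 9 pairs of a control and an shSamd14 library, genes with the first 8-base site were higher and genes with the second lower than genes without the words, by 0.034 to 0.144 and by -0.159 to -0.029 on the log2 scale. In the 6 pairs within a group these differences ran from -0.067 to 0.075 and from -0.081 to 0.061. The real split of the 6 libraries gave 327 genes past the threshold and was the 1 of 10 splits to give as many; the highest count of the other splits was 0. Each other split mixed control and shSamd14 libraries on both sides. Differences between the groups then add to the spread within a side and lower the count. The 10 splits are also too few for a share under 0.05, so no conclusion is drawn from them.

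The rise of megakaryocyte and platelet genes was weighed against 3 technical explanations. A lower share of the main cell type would raise markers of other lineages alike, but their median exceeded the pooled median of mast cell, granulocyte and monocyte genes (0.097, 82 genes) by 0.286 (95% bootstrap interval 0.164 to 0.469). With 1 library left out this difference was 0.221 to 0.533 in 5 of 6 fits, with intervals above 0. Without control replicate 3, the control library with most granulocyte reads, it was 0.07 (-0.016 to 0.206). The medians there were 0.362 for megakaryocyte genes and 0.292 for the pooled genes. Without both libraries numbered 3 the difference was 0.293 (0.092 to 0.377). This contrast depends on the libraries kept, so it does not exclude a lower share of the main cell type. A single library does not account for the rise of the list, since the lowest median with 1 library left out was 0.362 (0.29 to 0.433, without control replicate 3) against 0.383 with all. Nor do the words CTGATTA and TGATTAA, since the 23 searched members without them had a median of 0.367 (0.242 to 0.478). A biological difference, more megakaryocyte precursors or a shift towards their programme after Samd14 was lowered, or an effect of either hairpin on a regulator of these genes, may remain as hypotheses. How the sort on CD71 and Ter119 acted on megakaryocyte precursors was not tested.

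The lower values of glycolysis, hypoxia and cholesterol genes were weighed in the same way. Gene length and GC content explained 4.0% of the variance of log2 fold changes over 12549 genes, and with this trend removed the median of the 50 genes was -0.15 (-0.198 to -0.128) against -0.18 before. The 43 searched members without CAAGTGT or AAGTGTA had a median of -0.184 (-0.202 to -0.113). Without shSamd14 replicate 3 the median was -0.099 (-0.128 to -0.064), so a large part of the shift went with this library, and how far it alone may account for the pattern cannot be told. A difference in culture conditions between wells, such as density or oxygen, was not tested and may also contribute.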
